A study of Homo sapiens with 4 samples.

How the data were processed

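Total RNA from subcutaneous xenografts of U-87MG cells, an established human glioblastoma line, was labelled with biotin and hybridised to Affymetrix human gene arrays, per the labels' protocols. The starting amount was 100 ng, only RNA with an integrity number above 8 was carried forward, and the Affymetrix WT Plus chemistry was used. The data comprised 4 arrays, 2 for tumours injected with siRNA against VDAC1 and 2 for tumours injected with scrambled siRNA. Group and replicate number were taken from the sample titles. The labels do not say that the 2 arrays of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Nor do they say whether the groups were hybridised together or on the same array type, so a difference in processing would coincide with the group.

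The values used were log2 intensities per probe set as the authors deposited them. Per the submitters' processing notes, Partek and RMA were used; versions, settings and the role of each are not given in the sources used here. All 4 deposited columns of log2 values had the same mean, 5.35, over the 13523 probe sets of the table, while their medians were 5.17 and 5.20 in the arrays labelled VDAC1 siRNA and 5.03 and 5.09 in those labelled scrambled siRNA. The arrays had therefore been centred on a common mean over these probe sets but not given equal distributions over them, and how the probe sets of the table were chosen is not stated. Centring on the mean sets the balance between higher and lower genes. The number of arrays limits the precision.

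Probe sets were named through the array's platform annotation. Of the 13523 probe sets, 9847 carried 1 gene symbol, 832 carried several and 2844 were not listed in that annotation. Symbols were updated through the Entrez gene identifiers with the RefSeq gene table of assembly GRCh38.p14, which held 9842 of the 9847 and changed 0 symbols; the other 5 kept the symbol of the annotation. No coordinates are given, because the build behind the annotation was not tied to that assembly. For each gene the probe set with the highest mean over the 4 arrays was tested, which gave 9431 genes. Of these, 290 had more than 1 probe set, and for 28 the probe sets were called in opposite directions.

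The groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with group as the only term, and p-values were adjusted by the method of Benjamini and Hochberg over the 9431 genes. There were 2 residual degrees of freedom per gene, and the moderation added 9.00 prior degrees of freedom with a prior variance of 0.0624. An exact two-sided permutation test of 2 arrays against 2 cannot give a p below 0.333, so no such test is reported for single genes. A gene was called at an adjusted p under 0.05. A second, descriptive count took genes at least 1.5-fold apart with an unadjusted p under 0.05, and the interval of the share of higher genes among them is an exact 95% binomial one that treats genes as independent.

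Before the data were examined, 35 gene lists were fixed, covering metabolism, tumour growth, cell identity, stress responses, RNA quality and markers of other cell types that a tumour in a mouse could hold. A list was tested where at least 5 of its genes were measured, with limma's camera at a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 29 lists tested. The same test with a correlation estimated from the arrays and limma's fry were run as alternatives. The form with an estimated correlation rests on the 2 residual degrees of freedom and could call little here. A list that it did not call is therefore not argued against by it. The genes named were chosen by a rule fixed at the same time. It took VDAC1, VDAC2 and VDAC3, and then the 10 higher and 10 lower called genes with the largest log2 difference. For these, the arrays of the groups could not overlap and the higher group's mean had to lie above the median. Uncharacterised loci, small RNAs named as SNOR, MIR, RNU, RNA5 or RNY and pseudogenes were left out. From each list it took the 2 genes with the smallest p, or up to 4 where that many were called. A list that passed its test added up to 4 genes in its own direction. In all, 139 genes were taken.

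The fit was tested on simulated data with the 9431 genes, the spread of these arrays and 200 changed genes in each of 20 draws. It recovered 34.7% of genes changed by 1 on the log2 scale, 99.4% of those changed by 2 and 100% of those changed by 3, and 5.11% of its calls were false. A list made to change was found in 20 of 20 draws, and 0 of 600 unchanged lists were called. Genes were drawn independently of each other, whereas the correlation estimated from the arrays ran from -0.127 (neuronal list) to 0.943 (NF-kB list). Far more genes were called in the data than were changed in a draw. The simulated error rates therefore do not carry over to the lists or genes below.

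The alternatives fixed at the same time were quantile normalization of the deposited columns, centring on array medians, filters that kept the upper 50% of genes or left out the lowest 25% by mean level, an intensity trend with a robust prior, an ordinary linear model without moderation, all probe sets of the table, the mean of a gene's probe sets, the replicate number as a block, leaving out each array in turn, array weights, an adjusted p of 0.1 and a fold of 2. With the ordinary linear model, the lists were tested with limma's cameraPR on the unmoderated t statistics, in place of camera. A list lost there thus met a different test as well as no moderation. After the data were seen, each list's median was also set against 10000 random lists of the same size, drawn from other genes in 20 classes of equal size by the level in the scrambled siRNA arrays or over all arrays. The random genes were drawn independently of each other, so the percentile of a list whose genes vary together can be too extreme. Also chosen after the data were seen were a list of genes with ultraconserved exon sequence and a list of fast-evolving surface and immune proteins. Figures were drawn with matplotlib 3.10.9.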

Results

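U-87MG cells were grown as tumours under the skin of nude mice, which lack a working thymus and accept human cells. Per the labels, tumours that had reached 50 to 80 mm3 were assigned to siRNA against VDAC1 or to scrambled siRNA, a control sequence. Each tumour received 8 injections of 20 µl, given 3 days apart, with siRNA in a polyethylenimine carrier at 50 nM. VDAC1 encodes the voltage-dependent anion channel through which ATP, ADP and other metabolites cross the outer mitochondrial membrane. The design held 1 comparison, 2 arrays labelled VDAC1 siRNA against 2 labelled scrambled siRNA, and it addressed how gene expression in the tumours differed after injection of siRNA against this channel. Over all probe sets, Pearson's r across probe sets was 0.943 between the arrays labelled VDAC1 siRNA and 0.965 between those labelled scrambled siRNA, but only 0.266 to 0.461 between arrays of different groups. Probe sets are not independent replicates, and these coefficients describe the arrays only. Whether the groups were hybridised and processed together is not stated in the labels, so the differences between the groups below include any difference in processing.

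The mRNA of the targeted gene was not lower in the arrays labelled VDAC1 siRNA. VDAC1 (probe set 8114145) read 5.91 and 6.68 there and 5.69 and 5.53 in the arrays labelled scrambled siRNA, on the log2 scale. It was higher by 0.69 (SE 0.28, 1.61-fold, limma adjusted p = 0.0451), with means of 6.30 ± 0.55 and 5.61 ± 0.12 (SD, n = 2 arrays). This goes against the label, so the groups are called by their labels throughout, and every direction below is that of the arrays labelled VDAC1 siRNA relative to those labelled scrambled siRNA. The call rested on array 2 of the VDAC1 siRNA label, without which the difference was 0.30 (adjusted p = 0.344), and it did not hold without array 1 (0.77, adjusted p = 0.0963) or array 2 (0.61, adjusted p = 0.182) of the scrambled siRNA label. It was also lost under quantile normalization (0.67, adjusted p = 0.0699) and under centring on array medians (0.57, adjusted p = 0.0918). VDAC3, a related channel, fell by 2.17 on the log2 scale (adjusted p = 2.82e-05). The probe sets of VDAC2, the third channel of the family, disagreed. The brighter one fell by 1.64 on the log2 scale, from 8.14 to 6.49, while the other was higher by 1.48, and their mean gave no call (-0.08, adjusted p = 0.762).

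**Figure D1:**
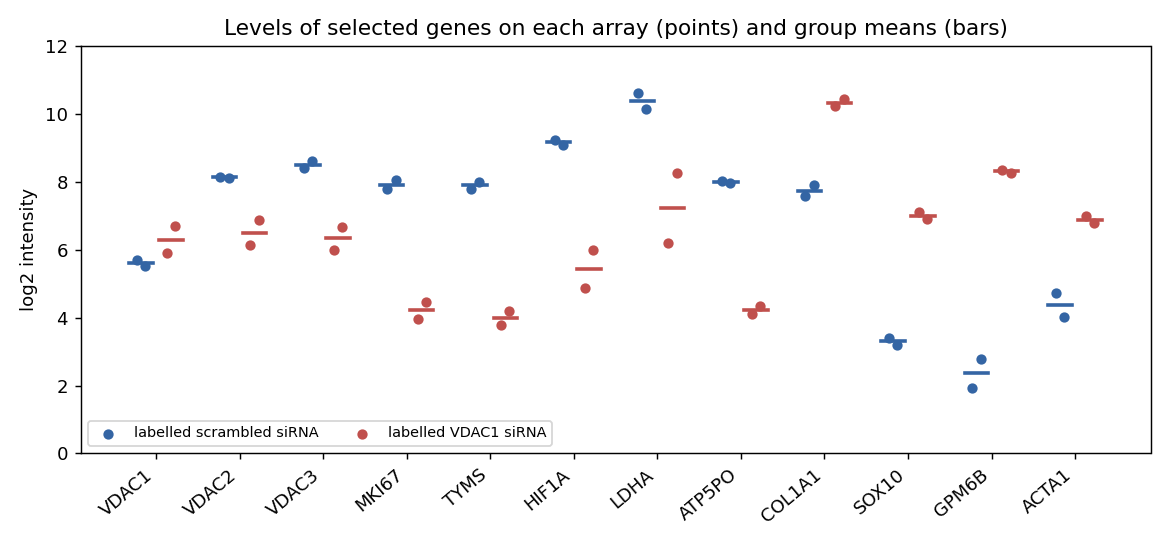
Log2 intensity of VDAC1, VDAC2, VDAC3 and 9 other named genes on each of the 4 arrays. Points are arrays, bars are means of 2 arrays, and blue and red mark the arrays labelled scrambled siRNA and VDAC1 siRNA; VDAC1 lay between 5.53 and 5.69 in the former and at 5.91 and 6.68 in the latter.

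Of the genes that the naming rule allowed, the largest increase was that of GPM6B, a proteolipid of neural cell membranes. It rose by 5.95 (SE 0.29) on the log2 scale. MID2, a ubiquitin ligase that binds microtubules, rose by 4.71, SCARNA11, a small Cajal body RNA, by 4.59, and RNF130, another ubiquitin ligase, by 4.34. NLGN3, a synaptic adhesion protein, rose by 4.03, FOXD3, a neural crest transcription factor, by 4.01, and NKAIN1, a partner of the sodium pump, by 3.99. TUBB2A, a beta-tubulin, rose by 3.96, GNAO1, the G protein alpha subunit abundant in neurons, by 3.92, and FXYD1, a regulator of the sodium pump, by 3.83. Among the allowed genes that fell, DCBLD2, a transmembrane receptor-like protein, changed most (-4.91, SE 0.57), followed by B2M, the light chain of MHC class I (-4.75, SE 0.67). GLIPR1, named for its expression in glioma, fell by 4.73 on the log2 scale, SKA2, a kinetochore protein, by 4.69, and LDHB, a subunit of lactate dehydrogenase, by 4.55. Differences of -4.53 for RPL35, a ribosomal protein, -4.52 for NT5E, an ectoenzyme that makes adenosine, and -4.50 for HSP90AA1, a stress-inducible chaperone, came next. TXN, thioredoxin, fell by 4.48 on the log2 scale and SLC38A2, an amino acid transporter, by 4.45. All 20 genes passed with limma, with adjusted p-values from 1.40e-06 to 7.24e-05, and for each of them both arrays of one label lay above both of the other. The naming rule required both. FOXD3, DCBLD2, B2M, GLIPR1, LDHB, RPL35, NT5E and HSP90AA1 were not called by an ordinary linear model without moderation (adjusted p from 0.0509 to 0.129). The scrambled siRNA readings of GPM6B (1.93 and 2.79), MID2 (2.66 and 2.43) and FOXD3 (2.71 and 2.02) lay below the 1st percentiles of those arrays (2.87 and 3.04), so the size of these differences rests on readings whose distance from background is unknown.

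Of 9431 genes tested, 6829 (72.4%) passed an adjusted p of 0.05 with limma, 3353 higher and 3476 lower in the arrays labelled VDAC1 siRNA. Of these, 5310 differed at least 2-fold, 2207 at least 4-fold and 391 at least 8-fold. By the descriptive count of 1.5-fold and an unadjusted p under 0.05, 6836 genes differed, of which 48.9% were higher (exact 95% binomial interval 47.7% to 50.1%). This balance is set by the centring of the arrays, which the interval leaves out. With array medians centred the share was 45.4%. The arrays of the groups did not overlap for 8079 genes (85.7%), where chance gives 33.3%. How the probe sets of the table were chosen is not stated, and a choice by signal or by change could raise the 72.4% and the 85.7%. Both shares describe only the genes of this table. Sorted by the level in the scrambled siRNA arrays, the median difference was 1.37 for the 2154 genes under 4 on the log2 scale and -2.34 for the 90 genes over 9. That level is one side of the difference, and with gene correlations of only 0.135 to 0.323 between arrays of different groups such a slope follows from the sorting. Sorted by the level over all arrays, the median difference had no steady slope. It was -0.17 for the 1079 genes under 4, 0.11 at 4 to 5 and 0.00 at 5 to 6. It was -0.22 at 6 to 7, -0.66 for the 292 genes at 7 to 8, -0.19 at 8 to 9 and 0.50 for the 43 genes over 9. For each gene list the percentile of its median is given among random lists matched on the scrambled siRNA level and then, in this order, among random lists matched on the level over all arrays, comparisons chosen after the data were seen.

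**Figure D2:**
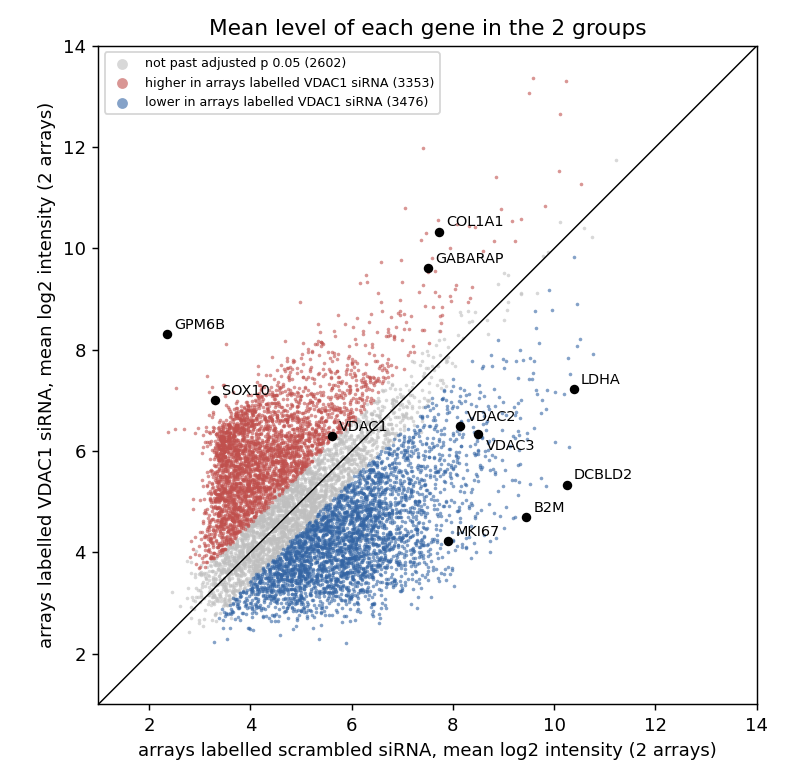
Mean log2 intensity of each of 9431 genes in the arrays labelled scrambled siRNA (horizontal) and VDAC1 siRNA (vertical), with the line of equal levels. Red points are the 3353 genes called higher, blue points the 3476 called lower and grey points the rest; named genes are marked in black.

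Genes of cell division were lower in the arrays labelled VDAC1 siRNA. Of 38 measured genes of the cell cycle list, 30 fell and 3 rose, with a median of -2.09 (limma camera adjusted p = 5.38e-06, but adjusted p = 0.834 with an estimated correlation). TYMS, the enzyme that makes thymidylate for DNA synthesis, fell by 3.90 on the log2 scale. MKI67, the proliferation antigen, went from 7.91 ± 0.19 to 4.21 ± 0.35 (SD, n = 2 arrays each) and so fell by 3.70 on the log2 scale, and KIF23 and KIF11, motors of the mitotic spindle, by 3.61 and 3.58. E2F1 (1.52), CDC25A (1.00) and UBE2C (0.67), which act in the onset of DNA replication and in mitosis, were the 3 that rose; they were named after their values were seen. The list's median lay at the 0.06 percentile of lists matched on the scrambled siRNA level and below all 10000 lists matched on the level over all arrays. Of 19 genes that MYC controls, 11 fell and 3 rose (adjusted p = 0.202), among them ODC1, the first enzyme of polyamine synthesis (-3.97), TFRC, the transferrin receptor (-3.01), NCL, nucleolin (-2.94), and WDR43, a ribosome assembly factor (-2.50). The p53 list was divided, with 5 genes up and 7 down of 18 (adjusted p = 0.901). MDM2, the ubiquitin ligase that restrains p53, fell by 2.99 on the log2 scale and ZMAT3, an RNA-binding protein, by 2.04, while BBC3, a killer protein of the BCL2 family also called PUMA, rose by 2.81 and PHLDA3, an inhibitor of AKT, by 2.33. Of 20 apoptosis regulators, 8 rose and 4 fell (adjusted p = 0.524). HRK, another BCL2-family killer protein, rose by 2.82 and ENDOG, a mitochondrial nuclease, by 2.22, and MCL1, which protects from apoptosis, fell by 3.40 on the log2 scale. The medians of the MYC, p53 and apoptosis lists lay at the 70.8, 45.5 and 51.4 percentiles in the first matching and at the 18.5, 40.8 and 68.4 percentiles in the second.

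Genes of respiration were lower as well. Of 43 nuclear-encoded subunits of the oxidative phosphorylation complexes, 28 fell and 3 rose, with a median of -1.22 (adjusted p = 0.000364; adjusted p = 0.834 with an estimated correlation). ATP5PO, a subunit of ATP synthase, fell by 3.78 on the log2 scale, COX7B (at 2.35 and 2.07 in the arrays labelled VDAC1 siRNA, below their 1st percentiles of 2.70 and 2.53) and COX6C, subunits of cytochrome c oxidase, by 3.67 and 3.50, and NDUFB5, a subunit of complex I, by 3.25. Of 21 genes of the TCA cycle, 16 fell and 3 rose, with a median of -1.25 (adjusted p = 0.0123; adjusted p = 0.834 with an estimated correlation). SUCLG2, a subunit of succinyl-CoA ligase, fell by 3.27 on the log2 scale, IDH3A, of isocitrate dehydrogenase, by 3.17, ME2, a malic enzyme, by 3.03; DLST, of the oxoglutarate dehydrogenase complex, differed by -2.57. The TCA cycle list was not called in the upper 50% of genes by level (adjusted p = 0.0523) or with an ordinary linear model (adjusted p = 0.346). How low these medians lay depended on the matching: they were at the 24.7 and 34.6 percentiles of lists matched on the scrambled siRNA level, but at the 0.03 and 0.71 percentiles of lists matched on the level over all arrays. Of 16 genes of cholesterol synthesis and its control, 11 fell and 2 rose, with a median of -1.77 (adjusted p = 0.0263; adjusted p = 0.853 with an estimated correlation) at the 0.19 and 0.03 percentiles. MSMO1, a sterol oxidase, fell by 4.38 on the log2 scale, SQLE, squalene epoxidase, by 3.14, HMGCS1, which makes the precursor of mevalonate, by 2.86 and EBP, a sterol isomerase, by 2.48. This list was not called without array 1 of the scrambled siRNA label (adjusted p = 0.0606), in the upper 50% of genes by level (adjusted p = 0.0675), without the lowest 25% (adjusted p = 0.0568) or with an ordinary linear model (adjusted p = 0.810).

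The rest of the metabolic lists had no call with camera. Of 23 mitochondrial carriers and import genes, 11 rose and 10 fell (adjusted p = 0.901). The list's median (0.46) and test direction were up while its mean was -0.01, and the median lay at the 99.8 and 83.3 percentiles. SLC25A4, the ADP/ATP carrier of muscle and heart, rose by 2.66, whereas SAMM50, of the outer membrane assembly machinery, SLC25A13, an aspartate/glutamate carrier, and TIMM17A, of the inner membrane translocase, differed by -2.38, -2.10 and -1.94. Of 14 genes of mitochondrial biogenesis, 6 rose and 6 fell (adjusted p = 0.875, median at the 50.6 and 35.9 percentiles), with ESRRA, a nuclear receptor, up by 2.35 and the chaperones HSPA9 and HSPD1 and the mitochondrial DNA packaging protein TFAM at -3.29, -2.76 and -2.55. Of 18 genes of serine, one-carbon and amino acid metabolism, 10 fell and 2 rose (adjusted p = 0.210, median at the 26.5 and 8.37 percentiles). MTHFD1 and MTHFD2, folate enzymes, fell by 2.77 and 2.36 on the log2 scale, ALDH18A1, of proline synthesis, by 2.01 and PHGDH, the first enzyme of serine synthesis, by 1.99. Of 21 genes of glycolysis and lactate handling, 9 fell and 2 rose (adjusted p = 0.517), and the median of -0.03 lay at the 99.8 percentile of lists matched on the scrambled siRNA level, whose own median was -1.24, but at the 63.2 percentile of lists matched on the level over all arrays, whose median was -0.20. LDHB is given above; LDHA, the other lactate dehydrogenase subunit, fell by 3.16 on the log2 scale, SLC2A3, a glucose transporter, by 2.58 and PFKP, a phosphofructokinase, by 1.92.

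HIF1A, the oxygen-regulated transcription factor, fell from 9.17 to 5.43, by 3.74 on the log2 scale. Of 22 genes of the hypoxia list, 12 fell and 2 rose (median -1.12, adjusted p = 0.163, 76.4 and 3.25 percentiles). ERO1A, an oxidase of the endoplasmic reticulum, fell by 2.12 on the log2 scale, while EGLN1, the hydroxylase that marks HIF1A for degradation, and MXI1, a MYC antagonist, rose by 1.96 and 2.20. The mean difference of this list was -0.99 with all arrays. It was -1.50 without array 2 of the scrambled siRNA label and -1.24 without array 2 of the VDAC1 siRNA label. The value with all arrays is the average of those without each array of a label. The fall was therefore smaller without the other array of either label. With an estimated correlation of 0.735, camera on all arrays gave an adjusted p of 0.922. Of 16 angiogenic factors, 5 rose and 6 fell (adjusted p = 0.901, 65.6 and 23.8 percentiles). HGF, the ligand of MET, and PDGFC, a growth factor, fell by 3.81 and 2.83 on the log2 scale, and VEGFB, of the VEGF family, rose by 2.16. The growth factor signalling list had 8 up and 8 down of 22 (adjusted p = 0.901, 92.3 and 40.4 percentiles). MET, the receptor of HGF, fell by 3.93 on the log2 scale, PHLDA1 by 2.24 and EGFR, the epidermal growth factor receptor, by 1.48, and ETV4, a transcription factor, rose by 1.60.

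Chaperones and antioxidant enzymes fell. Of 20 genes of the heat shock and oxidative stress list, 15 fell and 1 rose, with a median of -1.56 (adjusted p = 0.00429; adjusted p = 0.834 with an estimated correlation) at the 19.3 percentile of lists matched on the scrambled siRNA level and the 0.18 percentile of lists matched on the level over all arrays. NQO1, a quinone reductase, fell by 3.49 on the log2 scale, SOD1, a superoxide dismutase, by 2.86 and HSPH1, a chaperone, by 2.61, besides TXN and HSP90AA1. Of 16 genes of the unfolded protein response, 7 rose and 8 fell (adjusted p = 0.875, 57.9 and 30.6 percentiles). The endoplasmic reticulum proteins PDIA6, HSPA5 and CALR fell by 3.19, 2.51 and 2.20 on the log2 scale, and SDF2L1, of the same compartment, rose by 1.84. Of 21 genes of autophagy and the lysosome, 12 fell and 4 rose (adjusted p = 0.343, 48.2 and 8.63 percentiles). CTSL, a protease, LAMP2, a membrane protein, and NPC1, a cholesterol exporter of lysosomes, fell by 3.32, 3.28 and 2.60 on the log2 scale, and GABARAP, of autophagosomes, rose by 2.11. Of 14 immediate early genes, 8 rose and 2 fell (adjusted p = 0.202, 99.6 and 95.8 percentiles), with FOS and JUND, subunits of AP-1, up by 2.56 and 2.10, KLF2, a transcription factor, by 2.25 and CCN2, a matricellular protein, by 1.61. The mean difference of the immediate early list was 0.81 with all arrays and 1.07 without array 1 of the scrambled siRNA label. It was correspondingly smaller without the other array of that label. With an estimated correlation of 0.230, camera on all arrays gave an adjusted p of 0.922.

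Interferon and inflammatory genes had no common direction. Of 16 genes of the interferon list, 6 rose and 7 fell (adjusted p = 0.804, 5.88 and 44.1 percentiles). EIF2AK2, the kinase that senses double-stranded RNA, fell by 3.32 on the log2 scale and the interferon-induced genes IFI44 and IFI44L by 3.10 and 2.25, and IFI27, another, rose by 2.40. Of 17 genes of the NF-kB list, 2 rose and 2 fell (adjusted p = 0.855, 45.0 and 83.8 percentiles). RELB, an NF-kB subunit, and CXCL3, a chemokine, rose by 2.01 and 2.18. SOD2, a mitochondrial superoxide dismutase, read 3.47 and 5.30 in the arrays labelled VDAC1 siRNA and 8.27 and 5.47 in those labelled scrambled siRNA (adjusted p = 0.0108), and it was not called without array 1 of either label. The direction of the NF-kB list turned with 1 array: its mean difference was -1.32 without array 2 of the scrambled siRNA label and 1.68 without array 1. With an estimated correlation of 0.943, camera on all arrays gave an adjusted p of 0.922.

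Some markers of glial identity rose, but only 5 of 15 oligodendrocyte and 10 of 18 astrocyte genes were measured. A choice of probe sets by signal could have kept genes low under 1 label only where they were high under the other. SOX10, a transcription factor of the oligodendrocyte and neural crest lineages, read 7.10 and 6.91 in the arrays labelled VDAC1 siRNA and 3.41 and 3.19 in those labelled scrambled siRNA, an increase of 3.70 (SE 0.23). CLDN11, a tight junction protein of myelin, rose by 2.52 and CNP, a myelin enzyme, by 1.11. The scrambled siRNA means of SOX10 and CLDN11 were 3.30 and 3.48. Of the 2154 genes under 4 there, 1534 were called higher and 66 lower. Of 5 oligodendrocyte genes, 3 rose and 0 fell (adjusted p = 0.210, 75.9 and 81.0 percentiles). Of 10 astrocyte genes, 6 rose and 3 fell (adjusted p = 0.625, 99.9 and 92.4 percentiles), with APOE, a lipid carrier, up by 2.59, NFIA, a gliogenic transcription factor, up by 2.29, and the gap junction protein GJA1 and the secreted chaperone CLU down (-2.89 and -2.85). Of 5 neuronal genes, 2 rose and 1 fell (adjusted p = 0.901, 35.2 and 56.5 percentiles; median -0.03 but mean 0.11 and test direction up). NCAM1, an adhesion molecule, rose by 1.66 and GAP43, of growth cones, fell by 1.98 on the log2 scale. Of 11 genes of the glioma stem cell list, 3 rose and 3 fell (adjusted p = 0.901, 90.8 and 74.4 percentiles). Its median was 0.40 and its mean -0.04. NOTCH2, ITGA6 and CD44, surface receptors, fell by 2.32, 1.97 and 1.62 on the log2 scale. NOTCH1, also taken by the naming rule, rose. Its mean was 3.81 in the arrays labelled scrambled siRNA and 5.31 in those labelled VDAC1 siRNA. Of 27 chromatin modifiers, 12 rose and 7 fell (adjusted p = 0.343, 97.5 and 85.7 percentiles). KDM6B, a histone demethylase, rose by 2.53, DNMT3A, a DNA methyltransferase, by 2.28, TET3, which oxidises methylcytosine, by 2.21 and SIRT6, a deacylase, by 2.15. Of 24 ribosomal protein genes, 6 rose and 12 fell (adjusted p = 0.594, 99.8 and 37.5 percentiles), with RPS6 and RPS23 at -2.50 and -2.40 and RPL19 at 1.87.

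Genes of invasion and matrix moved apart. Of 20 genes of the mesenchymal list, 13 fell and 3 rose (adjusted p = 0.0813, 48.5 and 0.82 percentiles). TNC, a matrix glycoprotein, MMP2, a matrix protease, and TIMP1, a protease inhibitor, fell by 3.11, 2.98 and 2.54 on the log2 scale, and ZEB2, a transcription factor, rose by 2.71. The list's mean difference was -1.08 with all arrays, -1.30 without array 2 of the VDAC1 siRNA label and -1.15 without array 2 of the scrambled siRNA label. The fall was correspondingly smaller without the other array of either label. With an estimated correlation of 0.148, camera on all arrays gave an adjusted p of 0.853. Of 21 collagen and matrix genes, 8 rose and 9 fell (adjusted p = 0.974, 89.0 and 47.3 percentiles; down with camera, up with fry). THBS1, an inhibitor of vessel growth, rose by 3.39, COL1A1, fibrillar collagen, by 2.59 and HSPG2, perlecan, by 2.24, and LAMC1, a laminin chain, fell by 2.36 on the log2 scale. Of 10 fibroblast and pericyte markers, 3 rose and 2 fell (adjusted p = 0.875, 90.6 and 87.4 percentiles). NOTCH3, a receptor of pericytes, rose by 1.89, COL3A1, another collagen, by 1.80 (1.08 without array 1 of the scrambled siRNA label) and FAP, a protease of activated fibroblasts, fell by 2.99 on the log2 scale.

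Markers of other cell types were measured in small numbers, such as 3 of 19 skeletal muscle genes, and their lists were not tested. How the probe sets of the table were chosen is not stated. A choice by signal could have kept genes that were low under 1 label only where they were high under the other. The directions below are therefore descriptive. The 3 skeletal muscle genes measured rose, TNNT3 and TNNI2, of fast-muscle troponin, by 2.66 and 2.60 and ACTA1, muscle actin, by 2.51. Of 3 endothelial genes, EGFL7, a secreted endothelial protein, and SOX17, a transcription factor, rose by 2.87 and 2.77, and ENG, named after its value was seen, read -0.49 and was not called. Of 2 macrophage genes, TYROBP, an adaptor, rose by 2.58 and CD68, a lysosomal protein, fell by 2.35 on the log2 scale. ELANE, neutrophil elastase, was the 1 gene measured of neutrophils and lymphocytes and rose by 2.74. The skin and fat list and the erythroid list had 0 measured genes.

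**Figure D3:**
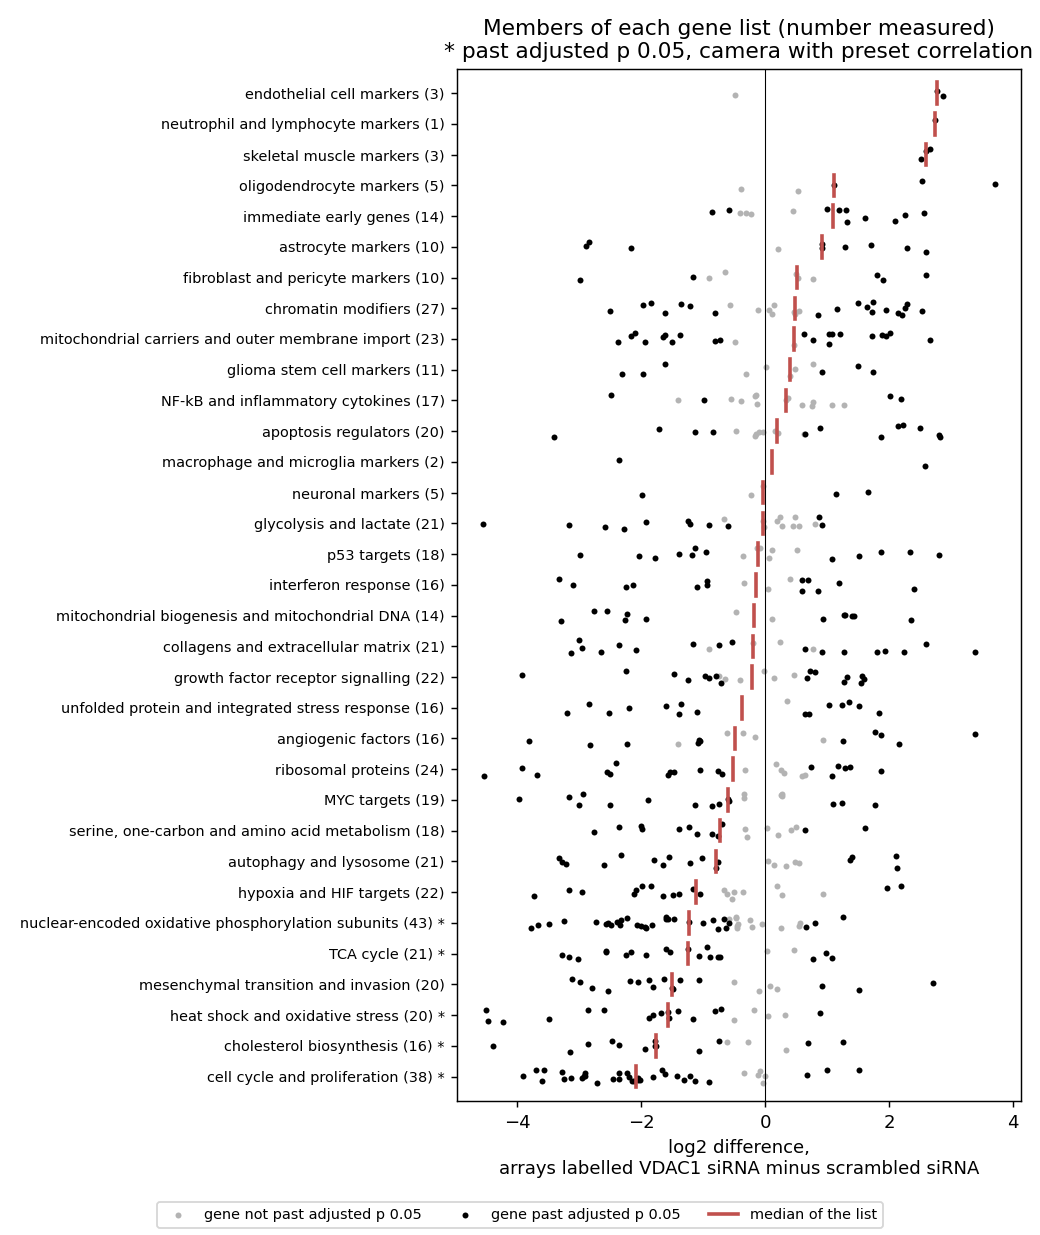
Log2 difference of each measured gene, arrays labelled VDAC1 siRNA minus scrambled siRNA, by gene list, ordered by list median. Black points passed an adjusted p of 0.05, grey points did not, red bars are list medians and asterisks mark the 5 lists past camera with the preset correlation.

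Adjusted over the list alone, the counts equalled those over all genes in every list except apoptosis (7 rose in place of 8) and immediate early genes (1 fell in place of 2). No list passed with an estimated correlation (0 of 29 adjusted, and 0 at an unadjusted p under 0.05), whereas fry, which does not compare a list with other genes, called 14. The correlations alone did not cause this loss. The serine list's estimated correlation was -0.0146, below the preset 0.01, yet its unadjusted camera p went from 0.0733 to 0.192. With 2 residual degrees of freedom that form of camera could call little, so it does not decide between the lists. An ordinary linear model without moderation called 3799 genes in place of 6829. On its t statistics, cameraPR called 1 list in place of 5, that of oxidative phosphorylation (cell cycle adjusted p = 0.150, heat shock adjusted p = 0.805). DCBLD2, B2M, LDHA, SLC2A3 and SOD2 were not called with an intensity trend and robust prior.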

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

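The test in this part was fixed only after the data were seen. Of the 2844 probe sets that the annotation does not list, which the comparison of genes did not use, 2283 (80.3%) passed an adjusted p of 0.05 in a limma fit over the whole table, 1327 higher and 956 lower in the arrays labelled VDAC1 siRNA. The share was 70.0% of the 9847 probe sets with 1 gene symbol and 78.8% of the 832 with several. The unlisted probe sets were singled out because they had not been analysed. What they measure is not given, and control probe sets of the array may be among them. The median absolute difference of the unlisted probe sets was 1.88, against 1.17 for those with 1 gene symbol and 1.53 for those with several. At least 16-fold differences were called for 172 of them and for 51 of those with 1 symbol. The unlisted probe sets were not uniform: the 1663 numbered below the lowest listed one held 158 of the 172 and had 632 higher and 703 lower (median -0.24), while the other 1181 held 14 and had 695 higher and 253 lower (median 1.28).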

How the results depend on the processing

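Across the alternatives fixed beforehand, 1849 of the values recomputed for the named genes kept their direction and side of the threshold, 55 kept only the direction and 0 reversed. Of the 55, 38 came from the ordinary linear model. Apart from VDAC1, VDAC2 and VDAC3, the named genes were taken by difference or p-value in these same arrays. That choice favours values that hold, so these counts do not describe genes in general. VDAC1 was not called under quantile normalization (0.67, adjusted p = 0.0699), centring on array medians (0.57, 0.0918), the ordinary linear model (0.69, 0.276) or the whole table (0.69, 0.0691), and with 1 array left out it ranged from 0.30 to 1.08 (adjusted p from 0.00579 to 0.344). Called genes numbered 3635 and 1.5-fold genes 3604 in the upper 50% by level, where fewer genes were tested, and 3799 were called by the ordinary linear model. With 1 array left out, 5905 to 6455 genes were called, the lone array being assumed to vary like the other group. On the t statistics of the ordinary linear model, cameraPR called 1 list, that of oxidative phosphorylation. Camera called 3 lists in the upper 50% by level, without the TCA cycle and cholesterol lists, and 4 without the lowest 25%, where the cholesterol list was lost. It called 0 with an estimated correlation, fry called 14, and 5 to 8 lists were called with 1 array left out. The share of higher genes was 45.4% with medians centred, which moved the median of all genes from -0.04 to -0.16. It was 50.4% without the lowest 25%, 50.6% with the ordinary linear model, 51.2% over the whole table and 47.7% to 50.2% with 1 array left out. Reversed results were the NF-kB list without array 2 of the scrambled siRNA label (-1.32, against 1.68 without array 1) and, in the matched comparison chosen after the data were seen, the glycolysis (1.20) and ribosomal lists (1.31 above random lists of the same scrambled siRNA level). Against lists matched on the level over all arrays these 2 lay at the 63.2 and 37.5 percentiles, within the range of random lists. Unless stated, the cause was not tested.

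Deviations of same-numbered arrays from their group means had a correlation of -0.0848 across probe sets, so the numbers only name samples. With the replicate block, 6571 genes were called, 6512 of them also called without it and in the same direction, VDAC1 gave 0.69 (adjusted p = 0.0426), and 7 lists passed, the hypoxia (adjusted p = 0.0491) and mesenchymal lists (adjusted p = 0.0385) besides the 5. Genes removed by a filter on level gave no value under it. How far intensity stood above background was not used here, so the lower limit of detection stays unknown.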

Other observations

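All tests in this part were chosen after the data were seen; that of the cell cycle list against lists matched on the scrambled siRNA level was set down before its own result was known. Of 11 microRNA genes, 10 rose and 0 fell by limma's adjusted p (median 2.98). Of 13 small nuclear RNA genes, which serve splicing, 10 rose and 3 fell (median 2.83). Small nucleolar RNA genes, which guide ribosomal RNA modification, went the other way, with 51 of 80 lower, 19 higher and a median of -1.28. The microRNA and small nuclear RNA medians lay above all 10000 random lists of the same size and level, and the small nucleolar RNA median below all of them, whether matched on the scrambled siRNA level or on the level over all arrays. Of 67 long noncoding RNA genes, 39 rose and 9 fell, with a median of 1.20, at the 88.6 percentile in the first matching and at percentile 100 in the second.

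Arrays with the same label differed in several lists. All 22 measured hypoxia genes were higher in array 1 than in array 2 of the scrambled siRNA label, by a median of 0.80, above all 10000 random lists matched on mean level. All 17 NF-kB genes were also higher there, by a median of 2.82, and 19 of 21 glycolysis genes were, by 0.62, 10 of 14 immediate early genes, by 0.50 (percentile 100), 14 of 16 cholesterol genes, by 0.31 (99.9 percentile), and 13 of 16 unfolded protein response genes, by 0.30. Fibroblast and pericyte markers went the other way, with 2 of 10 higher in array 1 and a median of -0.54, below all random lists, as did cell cycle genes (7 of 38 higher, median -0.21, 0.24 percentile) and collagen and matrix genes (9 of 21 higher, median -0.22, 0.65 percentile). SOD2 read 8.27 against 5.47, CXCL3 3.77 against 2.52 and SLC2A3 7.47 against 5.94. Between the arrays labelled VDAC1 siRNA, 17 of 22 hypoxia genes were higher in array 2, by a median of 0.42 (99.9 percentile), 14 of 20 heat shock genes by 0.46 (percentile 100), 11 of 16 unfolded protein response genes by 0.52, 10 of 16 cholesterol genes by 0.15 (97.6 percentile) and 11 of 17 NF-kB genes by 0.32. These values compare 1 array with 1 array and carry no test.

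The first pattern is the weak correlation between groups, 0.266 to 0.461. Scaling does not account for it, since after quantile normalization the highest correlation between groups was 0.461. Spearman's rank correlations, which a rescaling of an array's values leaves unchanged, were 0.0943 to 0.299 between groups and 0.926 and 0.954 within them. A general loss of signal cannot be told apart, because the arrays had been centred on a common mean, so that 99th percentiles higher by at least 0.75 in the arrays labelled VDAC1 siRNA decide nothing. RNA of the mouse host, read by human probes, may contribute: 30 genes with ultraconserved exons had a median of 0.28 (11 rose, 5 fell), at percentile 100 of lists matched on the scrambled siRNA level, and 20 fast-evolving surface and immune genes a median of -2.15 (0 rose, 18 fell), at the 0.01 percentile, although against lists matched on all arrays the first list lay at the 90.0 percentile and the second below all of them. Base composition cannot be told apart from this without probe sequences, as genes on GC-rich autosomes exceeded those on GC-poor ones by 1.30. An effect of the siRNA or of separate processing of the groups, on which the labels are silent, stays open and untested. So does the unstated choice of the probe sets in the table, which could itself lower the correlations.

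The second pattern is the higher VDAC1 mRNA in the arrays labelled VDAC1 siRNA. An exchange of 1 array between groups is argued against, since the lowest correlation within a group exceeded the highest between groups by 0.483. The general shift of genes at its level cannot be told apart, because these genes spread widely: the difference of 0.69 lay at the 84.0 percentile of the 1052 genes within 0.25 of its scrambled siRNA level (median -0.77, 5th to 95th percentile -2.37 to 1.47) and at the 67.0 percentile of the 965 genes within 0.25 of its level over all arrays (median -0.18). An exchange of both labels cannot be told apart from the labels as given, because no value in the table names the treatment. Whether mouse RNA read by the VDAC1 probe set contributed was not tested.

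The third pattern is the fall of cell division genes. The general fall of genes bright in the scrambled siRNA arrays was compared through lists matched on that level, whose median was -1.18. The list's median of -2.09 lay at their 0.06 percentile and below all lists matched on the level over all arrays. The random genes were drawn independently, whereas this list had an estimated correlation of 0.218. The percentiles may therefore be too extreme, and they do not exclude the general fall. A smaller share of human tumour RNA, base composition and, with the labels as given, fewer dividing tumour cells after injection of siRNA against VDAC1 may each contribute and were not separated.

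Of 224 genes called lower with a scrambled siRNA mean over 8, 89.3% were higher in array 2 than in array 1 of the VDAC1 siRNA label, with median differences of -2.17 and -2.98 from the scrambled siRNA mean, whereas over all 3476 lower genes the share was 46.5%.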
